A study of Sorghum bicolor with 9 samples.

How the data were processed

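Total RNA from leaves of wild-type Sorghum bicolor BTx623 was sequenced by the authors in 3 groups, control, moderate and severe saline-alkali soil, with 3 biological replicates each and 9 libraries in all. The processing notes name HISAT2 2.0.5 for alignment and DESeq2 1.20.0 for the authors' fold changes. The read counter, genome build, strandedness and adjustment method are not given in the sources used here. The deposited table holds 35281 genes, of which 5517 have no count in any library. Its raw counts, whole numbers deposited without normalisation with 1 column per library, were used for every main result. The FPKM values deposited by the authors equal the count divided by gene length and multiplied by a constant per library. The library size behind that constant follows median-of-ratios size factors, not the column totals, and gene length equals the genomic span for 34397 genes. The log2 fold changes deposited by the authors correlated with those computed here at r of 0.9989, 0.9987 and 0.9988 over genes for moderate against control, severe against control and severe against moderate. The deposited adjusted p-values of the authors were used only to count the authors' calls.

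Total counts ranged from 17792497 to 22449989 per library, so 3 counts, the number a count of 0 allows, correspond to 0.134 to 0.169 CPM (reads of a gene scaled to the total of the library). Reads without molecular identifiers are not independent molecules, so floors and intervals cover counting error only. Differences between replicates of a group exceeded counting noise in each pair, with chi-square per degree of freedom of 18.9 to 339.

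Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr with the 3 groups (22356 of 35281), scaled by TMM, and fitted with edgeR's quasi-likelihood model with 1 mean per group and all 9 libraries sharing the estimate of spread. The 3 contrasts were tested by the quasi-likelihood F-test, 2-sided, with Benjamini-Hochberg adjustment per contrast and a threshold of 0.05. Standard errors (SE) were computed as the absolute log2 change divided by the normal quantile of its p-value. Normalised CPM use the TMM-scaled library total. Where a group had no count over its libraries, the pooled counts of the other group were set against 3 counts over the group. That fold is a lower bound for counting error only, and single libraries can lie below it. Where it had 1 to 3 counts, the ratio is given with a 95% counting interval. Gene sets were tested by camera with a preset inter-gene correlation of 0.01 and again with the correlation estimated per set, and by fry, whose directional test asks whether a set's genes move one way on balance and compares them with no other genes.

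The tests, their alternatives, the rule for named genes and 39 gene lists defined by words in gene names were fixed before the data were examined. The table gives descriptive names only to 254 loci outside the reference annotation, and otherwise 1 of 636 protein family labels for 11025 genes (8005 tested). The list words were therefore matched to the family labels, which count as descriptive names here. Of the 39 lists 33 held no tested gene, all 6 ABA lists among them, and 4 held at least 3: catalases for antioxidant enzymes, HSP70 for heat shock proteins, lipoxygenases for jasmonate and thaumatin-like proteins for pathogenesis-related genes. After the data were seen, camera was added on each of 188 family labels with at least 10 tested genes, on 6 smaller families (SPX, RPE65, Catalase, Clp_N, EIN3 and GSHPx, adjusted among themselves), and families were matched to the themes of the lists by what they are known for. Of the 6 smaller families only SPX was called. The others had adjusted p = 0.324 to 0.787 for moderate and 0.943 for severe against control.

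The rule for named genes took, per contrast, genes past the threshold with a family label, a mean of at least 5 CPM and no overlap between the 2 groups, the 5 with the largest rise and the 5 with the largest fall, and from each list up to 3 members with the smallest adjusted p in each comparison with control. For families it was applied in the same way after the data were seen, and the examples printed were picked from the genes it gave with their values known. The groups of each named gene called do not overlap, so each direction holds in 3 of 3 libraries against 3 of 3.

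The procedure was tested on simulated data with known changes, negative binomial counts of 22356 genes at each gene's spread in the 9-library fit, with changed genes drawn from those at or above 5 CPM. For moderate against control, edgeR called 0 of 50 genes changed by 1 on the log2 scale (34 at an unadjusted p under 0.05), 26 of 50 at 2, 43 at 3 and 50 at 4. The steps at 3 and 4 were added after a first run. For severe it called 1, 24, 42 and 50. Of 22156 and 22136 unchanged genes 5 each were called. The simulations held far fewer changed genes than the data, which makes the adjusted threshold stricter there, so these shares are not those of the data. A simulated set of 20 genes raised 2-fold passed camera with adjusted p = 2.14e-16, and 0 of 188 other families did (4 at an unadjusted p under 0.05). Simulated genes were drawn independently, with the same spread in each group. The simulation therefore does not test camera on genes that move together. Nor does it test the gene calls where severe replicates spread more than the others.

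Alternatives were DESeq2's size factors in edgeR (RLE), DESeq2, no low-count filter, a filter of at least 1 CPM in at least 3 samples, a fold threshold, fits with only the 2 groups compared, limma on log2(FPKM + 1), the replicate number as a block, and leaving out each library in turn. Total counts as the only scaling and limma voom with a weight per group were added after the data were seen. Medians of families were also computed with genes at 0 set to their bound, and 2 of 162 moved by more than 0.1. The sharing of the 3 controls by both stress comparisons was studied in 20 simulations of unchanged groups. Values derived from the ABA lists could not be computed, since no gene was placed in them.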

Results

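RNA sequencing measured transcripts in leaves of wild-type Sorghum bicolor BTx623, the inbred line behind the sorghum reference genome, sampled when the seedlings had 4 leaves. The plants grew under normal conditions (control), in moderately saline-alkali soil (3‰ salt, pH 8.1) or in severely saline-alkali soil (5‰ salt, pH 8.1). These salt values follow the sample titles and the series design, while another tag of the stressed samples gives the same digits in percent, 10 times as much. Each group held 3 biological replicates, 9 libraries in all. The control soil's salt content and pH are not given in the sources used here. Assigned reads per library totalled 20923148, 19511983 and 19481164 in control replicates 1 to 3, 17966323, 21130553 and 22449989 in moderate and 20543646, 21842574 and 17792497 in severe. A count of 0 in a single library allows up to 3 counts, or 0.134 to 0.169 CPM (reads of a gene scaled to the total of the library), for counting error only. Group values below are mean CPM, normalised between libraries, ± SD (n = 3 libraries). Chromosome positions are those in the deposited table, whose genome build is not given in the sources used here.

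The severe libraries stood apart from the other 6. The first principal component held 73.9% of the variance and set the severe libraries, at scores of 202.8 to 317.9, apart from control and moderate libraries, at -151.2 to -98.2. The second held 12.2% and parted moderate (78.6 to 105.8) from control (-87.7 to -79.1). Severe replicates also differed most among themselves, with a biological coefficient of variation of 60.8%, against 24.7% in control and 26.3% in moderate. Severe replicate 1 had a normalisation factor of 0.512, against 0.858 and 0.973 for severe replicates 2 and 3 and 1.33 to 1.41 for moderate. The 10 most abundant genes took 11.2 to 12.6% of reads in severe, 8.23 to 10.7% in control and 5.43 to 6.29% in moderate.

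**Figure D1:**
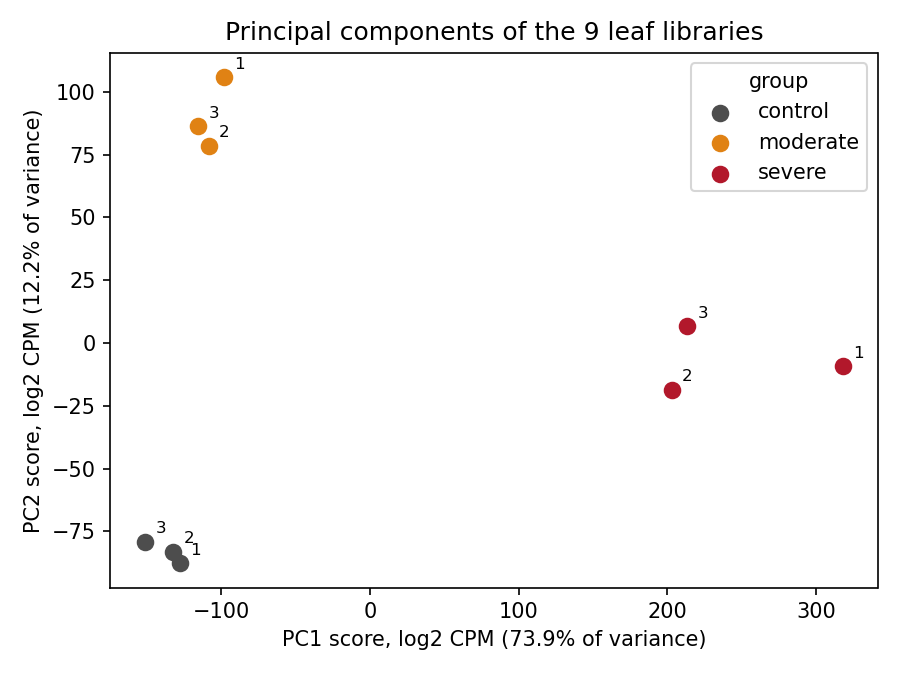
Scores of the 9 leaf libraries on the first component (horizontal, 73.9% of variance) and the second (vertical, 12.2%) of log2 CPM, with colours for groups and digits for replicate numbers. The 3 severe libraries sit at first-component scores of 202.8 and above, and the control and moderate libraries at -98.2 and below.

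Moderate stress against control asked which leaf transcripts differed in soil of 3‰ salt. Genes with an SPX domain, the domain of phosphate-status sensors, stood out. Of 9 tested, 8 rose and 0 fell, with a median log2 change of 3.03. Sobic.001G259100 (chromosome 1, 31011171 to 31012741) averaged 0.311 ± 0.191 CPM in control and 196 ± 256 in moderate, a log2 rise of 9.28 (SE 2.24), and its 3 moderate libraries read 490, 28.1 and 70.3 CPM (log2 rise 7.31 and mean 49.2 without moderate replicate 1). Sobic.003G183600 went from 0.424 ± 0.38 (0.206 without control replicate 3) to 140.3 ± 148 CPM, with moderate libraries at 309.6, 35 and 76.2 (mean 55.6 without moderate replicate 1). Sobic.004G084900 (chromosome 4, 7048315 to 7052007) went from 5.48 ± 0.402 to 59.9 ± 28.1 CPM, a log2 rise of 3.45 (SE 0.77) with adjusted p = 0.00162 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The SPX family as a group passed camera with Benjamini-Hochberg adjusted p = 1.57e-07, in a test added after the values were seen, and did not pass with an estimated correlation (adjusted p = 0.305). Without control replicate 2 the number of SPX genes that rose was 5.

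The series title names abscisic acid (ABA) biosynthesis, catabolism and signalling. No gene in the table carried a name that placed it in any of the 6 ABA lists fixed beforehand. Protein families that include known ABA components were counted instead. Their labels do not tell which members act in ABA, so these counts and genes are no measure of ABA synthesis or signalling. Of 71 type 2C protein phosphatases (PP2C), the family that includes the ABA co-receptors, 13 rose and 3 fell under moderate stress. Sobic.009G161800 (chromosome 9, 51880214 to 51882333) averaged 7.02 ± 1.64 CPM in control and 62.7 ± 9.72 in moderate, a log2 rise of 3.16 (SE 0.69) with adjusted p = 0.00137 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Sobic.003G198200 went from 6.72 ± 1.52 to 36.5 ± 2.42 CPM. Sobic.006G018400 had 2 counts over the control libraries and 269 over the moderate ones, a ratio of 93.8 with a 95% counting interval of 25.7 to 778. Of 60 basic leucine zipper factors (bZIP_1), the family of the ABA-response-element binding factors, 12 rose and 2 fell. Sobic.003G368300 rose from 1.87 ± 0.757 to 13.6 ± 4.15 CPM and Sobic.003G021800 fell from 30.4 ± 13.6 to 1.76 ± 0.581. The PP2C family did not pass camera in this comparison. The bZIP_1 family passed, but not without moderate replicate 1 and not with an estimated correlation. Carotenoid cleavage dioxygenases (RPE65) include the 9-cis-epoxycarotenoid dioxygenases that commit carotenoids to ABA, but the label does not tell which members these are. None of the 4 tested passed. The most abundant of them, Sobic.004G268500, averaged 1405 ± 474 CPM in control and 428 ± 23.1 in moderate (log2 change -1.72 (SE 0.90), adjusted p = 0.169 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It passed with only the 6 control and moderate libraries in the fit (adjusted p = 0.00238) and without severe replicate 3 (adjusted p = 0.0437).

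Several other families had more members higher than lower in moderate leaves. Of these, Myb, HMA, GRAM, DUF6 and aldehyde dehydrogenases passed camera, and NAC and heat shock factors did not. None passed with an estimated correlation. Of 137 Myb factors, 33 rose and 4 fell. Sobic.009G253300 went from 1.43 ± 0.61 to 47.5 ± 4.77 CPM (log2 5.05 (SE 1.01)) and Sobic.006G192100 from 2.83 ± 0.768 to 46.9 ± 5.58. Of 32 proteins with a heavy-metal-associated domain (HMA), 9 rose and 1 fell, and Sobic.004G164200 went from 23.6 ± 10.4 to 461 ± 78.1 CPM. Of 12 GRAM-domain proteins 5 rose and 1 fell. Sobic.001G212000, with 3 counts over the control libraries and 826 over the moderate ones, changed by a ratio of 192 (95% counting interval 65.5 to 933), or 99.5 without moderate replicate 2. Its 3 control counts were all in control replicate 1, without which the control mean was 0 CPM. Of 33 proteins with the DUF6 domain, found in membrane transporters, 7 rose and 1 fell. Aldehyde dehydrogenases had 3 of 14 higher and 0 lower, and Sobic.003G203600 went from 2.85 ± 1.72 to 67 ± 20.9 CPM. Of 68 NAC factors (NAM), 10 rose and 3 fell, among them Sobic.008G021800 from 1.25 ± 0.408 to 31 ± 5.45 CPM. The NAC gene Sobic.005G018500 rose by 6.90 (SE 1.83) on the log2 scale, or 5.82 without moderate replicate 1 and 7.60 without control replicate 1. Of 22 heat shock factors, 4 rose and 1 fell, with Sobic.010G164400 at 0.381 ± 0.226 CPM in control (0.253 without control replicate 1) and 14.5 ± 3.73 in moderate and Sobic.004G101400 at 1.44 ± 0.264 and 29.9 ± 13.7.

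Camera called 6 families lower in moderate leaves, none of them with an estimated correlation (adjusted p = 0.656 to 0.731 for all 19 called), and 5 are described here. Of 28 translational GTPases of the elongation factor Tu type (GTP_EFTU), 11 fell and 1 rose, with a median log2 change of -0.72. Sobic.006G161500 went from 1162 ± 129 to 228 ± 47 CPM. Of 15 rhodanese-domain proteins 7 fell and 1 rose, with Sobic.003G387800 at 544 ± 67.5 CPM in control and 97.3 ± 16 in moderate (log2 -2.48 (SE 0.56)). Of 16 ferredoxin-type proteins (Fer2) 6 fell and 1 rose, and Sobic.007G004800 went from 1030 ± 296 to 46.7 ± 14 CPM. Of 21 FKBP-type prolyl isomerases 6 fell and 2 rose, and Sobic.010G219500 went from 124 ± 10.4 to 16.6 ± 1.21 CPM. Of 62 DEAD-box RNA helicases 5 fell and 0 rose, so most members did not pass. With total counts as the only scaling, the GTP_EFTU split was 2 lower and 1 higher.

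Ion transport and defence families, and the fixed lists, are given beside the 17.1% of all tested genes called in this comparison. Of 13 sodium and cation exchangers (Na_H_Exchanger), 2 rose and 0 fell: Sobic.002G156000 from 24.3 ± 2.2 to 58.8 ± 1.91 CPM and Sobic.005G201000 from 20.3 ± 2.01 to 51.3 ± 4.01. Of 22 potassium transporters (K_trans), 2 rose and 0 fell, Sobic.004G250700 by 0.99 (SE 0.33) and Sobic.006G061300 by 2.08 (SE 0.74) on the log2 scale, and both calls were lost without any 1 of the control libraries, or without moderate replicate 2 or 3, the second also without moderate replicate 1, while the changes stayed at 0.94 to 1.05 and 1.80 to 2.48. The antioxidant list came down to 3 catalases, of which 1 fell (Sobic.001G517700, from 1123 ± 133 to 336 ± 51.7 CPM). Adjusted over the list alone, 1 catalase rose and 1 fell. The jasmonate list came down to 12 lipoxygenases, with 2 higher and 1 lower (3 and 1 adjusted over the list alone), and Sobic.001G125700 rose from 1.6 ± 0.489 to 32.2 ± 8.3 CPM. The pathogenesis-related list came down to 26 thaumatin-like proteins, with 0 higher and 2 lower (also 0 and 2 adjusted over the list alone), and Sobic.001G439100 fell from 38.4 ± 9.64 to 0.573 ± 0.351 CPM. The heat shock list came down to 20 HSP70 chaperones, with 3 higher and 2 lower (4 and 2 adjusted over the list alone). Sobic.003G350700 rose from 6.12 ± 1.72 to 47.5 ± 10.7 CPM and Sobic.001G129000 fell from 475 ± 72.3 to 83.6 ± 4.52. The HSP70 median was -0.07 and its mean 0.296 on the log2 scale. None of these 4 lists passed camera (Benjamini-Hochberg adjusted p = 0.126 for lipoxygenases and thaumatin-like proteins, 0.243 for catalases and 0.972 for HSP70). With an estimated correlation these were adjusted p = 0.454, 0.63, 0.454 and 0.987. By camera 1 list was under an unadjusted p of 0.05, and fry called 2. Without control replicate 3, thaumatin-like proteins passed as lower (adjusted p = 0.0303). With total-count scaling the members higher and lower were 1 and 1 for catalases and 2 and 2 for thaumatin-like proteins.

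Of 22356 genes tested, 3825 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment between moderate and control, 1998 higher and 1827 lower, and 3387 of them changed at least 2-fold. In 55.9% of tested genes the 2 groups' values did not overlap, where chance gives 10%. Total-count scaling gave 3707 higher and 704 lower, as it moves the median log2 change of all genes by 0.477. Of 188 families, 19 passed camera with Benjamini-Hochberg adjustment (13 up, 6 down), and none did with an estimated correlation (adjusted p = 0.656 to 0.731 for those 19; 9 families at an unadjusted p under 0.05; fry called 57). The 13 called higher were Myb, HMA, DUF6, GRAM, bZIP_1, MFS_1, 2OG-FeII_Oxy, Ras, PFK, Aldedh, zf-Dof, Sugar_tr and Pkinase, and the 6 called lower were GTP_EFTU, Rhodanese, DEAD, FKBP_C, Fer2 and RRM_1. At least 19 families passed in 3 of the 10 splits of these 6 libraries into 3 and 3, the real one included. RRM_1, the RNA recognition motif family, had 8 of 203 genes higher and 17 lower, which turned to 15 and 4 with total-count scaling. Calls lost without a single library were bZIP_1 and 2OG-FeII_Oxy (moderate replicate 1), Fer2 (moderate replicate 2, severe replicate 1), PFK and Ras (control replicate 3), Aldedh (control replicate 2), Pkinase (control replicate 3, moderate replicate 3), Sugar_tr (control replicate 3, moderate replicate 1, severe replicate 2) and zf-Dof (control replicates 1 and 2, moderate replicate 1, severe replicate 2). The larger side turned with limma on log2(FPKM + 1) (2375 higher, 2602 lower) and without control replicate 1 (693 and 795), 2 (734 and 865) or 3 (983 and 1031) or severe replicate 1 (3676 and 3692). The gene count changed with the libraries in the fit. It was 9503 with only these 6 libraries, which included 3766 of the 3825, in a fit that also filtered and scaled anew (21109 genes tested), and 7368 without severe replicate 1. It was 1488, 1599 and 2014 without control replicates 1, 2 and 3, and 1657, 2007 and 1616 without moderate replicates 1, 2 and 3. The authors' deposited adjusted p-values called 9999 genes, which included 3805 of the 3825.

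Severe stress against control asked the same of soil with 5‰ salt. HSP70 chaperones, heat shock factors and universal stress proteins had more members higher than lower. Of 20 HSP70 chaperones 11 rose and 2 fell (the same adjusted over the list alone), with a median log2 change of 1.47. Sobic.003G350700 (chromosome 3, 67021779 to 67024939) went from 6.12 ± 1.72 CPM to 1468 ± 704, a log2 rise of 7.91 (SE 1.48) with adjusted p = 1.46e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Sobic.001G418600 had 3 counts over the control libraries and 20497 over the severe ones, a ratio of 8580 (95% counting interval 2930 to 41600), or 5640 without severe replicate 3. Of 22 heat shock factors 15 rose and 4 fell, and Sobic.010G164400 (chromosome 10, 48575060 to 48577328) went from 0.381 ± 0.226 (0.253 without control replicate 1) to 163 ± 60.5 CPM. Of 23 universal stress proteins (Usp) 17 rose and 2 fell, with a median of 2.24, and Sobic.003G319000 and Sobic.009G159400 rose by 3.54 (SE 0.70) and 2.91 (SE 0.58) on the log2 scale. Other chaperone families were not called: of 73 J-domain proteins (DnaJ) 34 rose and 19 fell (22 and 21 with total-count scaling; camera with Benjamini-Hochberg adjusted p = 0.236), and of 5 Clp proteins (Clp_N) 2 rose and 1 fell (1 and 2 with total-count scaling; adjusted p = 0.943). The heat shock list passed camera with Benjamini-Hochberg adjusted p = 0.00177, and not with an estimated correlation (adjusted p = 0.355). It was the only list of the 4 to pass. As families among 188, Usp (Benjamini-Hochberg adjusted p = 0.00202), HSP70 and heat shock factors (0.0329 each) and the AP2 factors (0.0357) passed camera as higher, and none did with an estimated correlation (adjusted p = 0.714 each). The libraries behind these rises are those with the coefficient of variation of 60.8%. At least 5 families passed in 8 of the 10 splits of the severe and control libraries into 3 and 3. At least 1 list passed in 9 of them, the real split included in both counts.

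The same families that hold ABA components were counted under severe stress, where calls over all tested genes also rose, from 3825 to 14858 of 22356. With only the 2 groups compared in each fit the calls were 9503 and 12659, so the size of that rise depends on the fit. Of 71 PP2C genes 35 rose and 19 fell. Sobic.006G018400 (chromosome 6, 3076063 to 3082312) had 2 counts over the control libraries and 4242 over the severe ones, a ratio of 2660 (95% counting interval 737 to 22000). Sobic.003G242200 averaged 0.0867 ± 0.0624 CPM in control (0.0506 without control replicate 1) and 112 ± 22.6 in severe, Sobic.003G198200 6.72 ± 1.52 and 243 ± 55.1, and Sobic.009G161800 7.02 ± 1.64 and 251 ± 95.8. Of 60 bZIP genes 30 rose and 12 fell. Sobic.001G044300 rose by 9.23 (SE 1.53) on the log2 scale to 44.7 ± 8.02 CPM, Sobic.003G368300 rose to 119.5 ± 37.1 CPM, and Sobic.004G031100 fell from 37.5 ± 7.37 to 0.236 ± 0.129. Among the 4 RPE65-type dioxygenases 2 fell and 0 rose. Which of them, if any, act in ABA synthesis is not known here. Sobic.004G268500 (chromosome 4, 61268235 to 61270278) went from 1405 ± 474 to 43.5 ± 49.2 CPM, a log2 change of -5.01 (SE 1.40) with adjusted p = 0.00118 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Its severe libraries read 25.5, 99.2 and 5.9 CPM, and the change was -6.50 without severe replicate 2 (mean 15.7 CPM) and -4.41 without severe replicate 3. Sobic.001G509200 went from 500.5 ± 48.9 to 194 ± 44.4 CPM. The PP2C and bZIP families did not pass camera in this comparison.

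Other stress-linked regulators, and the jasmonate families, had more members higher than lower. Of 86 AP2/ERF factors (AP2) 34 rose and 10 fell, with Sobic.009G212500 up by 8.09 (SE 1.53) and Sobic.006G058732 by 7.77 (SE 1.53) on the log2 scale. Of 68 NAC factors 33 rose and 16 fell, and Sobic.008G021800 reached 166 ± 38.2 CPM from 1.25 ± 0.408. Of 15 TIFY proteins (Zim), the family of the jasmonate repressors, 10 rose and 2 fell, and Sobic.001G482800 went from 0.208 ± 0.143 (0.127 without control replicate 1) to 30.7 ± 14 CPM. Of 12 lipoxygenases 8 rose and 2 fell (the same adjusted over the list alone), with Sobic.001G125900 from 87.9 ± 16.2 to 599.8 ± 59.7 CPM and Sobic.004G078600 from 3833 ± 591 to 134 ± 57.5. That list did not pass camera (Benjamini-Hochberg adjusted p = 0.175, and adjusted p = 0.355 with an estimated correlation). Of 26 thaumatin-like proteins 9 rose and 5 fell (the same adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 0.732, and adjusted p = 0.84 with an estimated correlation), and Sobic.003G331700 rose from 1.4 ± 0.668 to 3046 ± 2028 CPM (1880 without severe replicate 1). All 3 catalases changed, 1 higher and 2 lower, also adjusted over the list alone: Sobic.010G274500 went from 75.4 ± 6.14 to 1274 ± 647 CPM, Sobic.004G011566 from 1771 ± 186 to 336 ± 271 (201 without severe replicate 3) and Sobic.001G517700 from 1123 ± 133 to 613 ± 104. The call on Sobic.001G517700 was lost without control replicate 1 (log2 -0.79, adjusted p = 0.0737) or severe replicate 2 (-0.76, adjusted p = 0.0561), with the 2 groups alone (-0.87, 0.0503) and with the scaling of DESeq2 (-0.76, 0.0501), against -0.87 (SE 0.35) with all libraries. The catalase median was -0.874 and the mean 0.268 on the log2 scale, with adjusted p = 0.732 by camera with Benjamini-Hochberg adjustment and 0.84 with an estimated correlation. Of 13 sodium and cation exchangers 6 rose and 2 fell, and Sobic.001G522100 rose by 3.33 (SE 0.70) on the log2 scale. Of 22 potassium transporters 11 rose and 6 fell, and Sobic.002G001800 went from 54.5 ± 4.08 to 0.136 ± 0.0695 CPM.

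Genes with the NB-ARC domain, the nucleotide-binding domain of plant resistance receptors, had more members lower than higher. Of 208 tested, 101 fell and 29 rose, with a median log2 change of -1.34. Sobic.007G060900 (chromosome 7, 6388315 to 6400281) went from 61.9 ± 4.72 to 2.43 ± 0.828 CPM, a log2 change of -4.65 (SE 0.85) with adjusted p = 1.17e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Sobic.005G222900 went from 13.3 ± 5.18 to 0.144 ± 0.0755 CPM, and Sobic.005G183300 had no count in the severe libraries, at least 186-fold lower than in control against 3 counts over the group. Sobic.010G276800 rose from 11.1 ± 1.82 to 215 ± 39.1 CPM. The NB-ARC family passed camera with Benjamini-Hochberg adjusted p = 0.0357 and did not with an estimated correlation (adjusted p = 0.714), without control replicate 2, without severe replicate 1 or without the low-count filter. Lists of 208 genes matched on abundance and length also had medians under that of all tested genes (-0.775 against -0.189). FKBP-type isomerases had 14 of 21 lower and 4 higher, rhodanese-domain proteins 9 of 15 lower and 1 higher and GTP_EFTU proteins 13 of 28 lower and 6 higher. Sobic.003G387800 went from 544 ± 67.5 to 30.7 ± 9.6 CPM and Sobic.004G202200 from 1344 ± 101 to 68.7 ± 33. None of these last 3 families passed camera in this comparison.

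**Figure D2:**
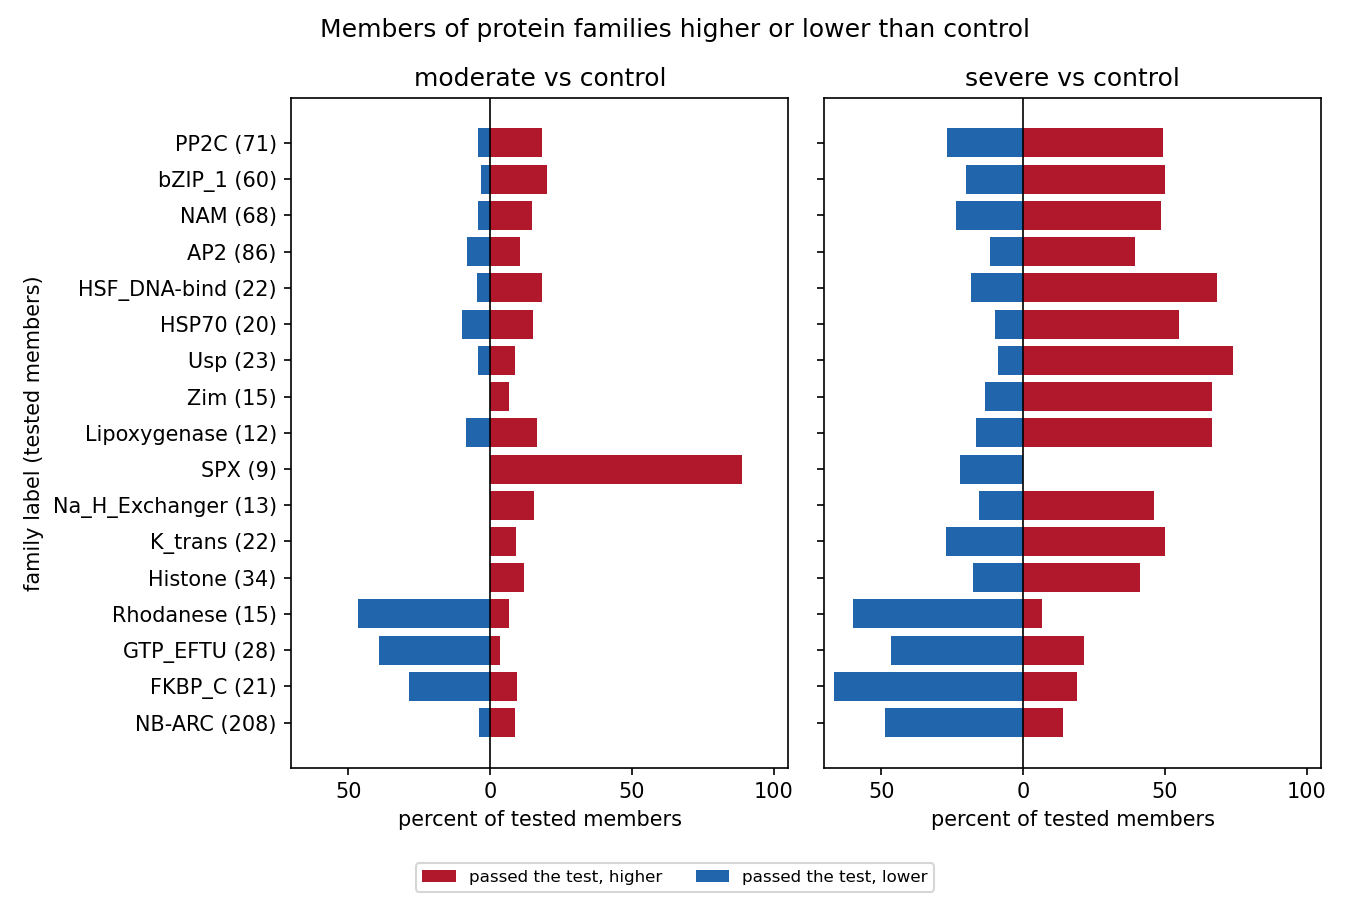
Percent of the tested members (horizontal axis) of 17 protein families (rows, tested members in brackets) that passed the test as higher (red, right) or lower (blue, left) than control, in moderate (left panel) and severe (right panel). SPX genes are higher in moderate (8 of 9) and not in severe (0 of 9), Usp, HSP70 and heat shock factors are mostly higher in severe and NB-ARC genes more often lower than higher there, and no family drawn changes its larger side with total-count scaling.

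Several of the steepest changes in severe leaves among genes with a family label were in metabolic enzymes. The cytochrome P450 gene Sobic.007G003500 went from 0.0683 ± 0.0285 to 2338 ± 2483 CPM, and its severe libraries ranged from 38.5 to 4971 (mean 1020 without severe replicate 1). The malic enzyme gene Sobic.003G292400 had 3 counts over the control libraries and 21229 over the severe ones, a ratio of 8880 (95% counting interval 3040 to 43100). Those 3 control counts were all in control replicate 3, without which the control mean was 0 CPM. Sobic.002G413200, a UDP-glycosyltransferase, and Sobic.006G162100, a glyoxalase-family gene, had no count in control. With the severe libraries pooled they were at least 1060-fold and 703-fold higher against 3 counts over the control group. The severe libraries of Sobic.006G162100 read 125.2, 16.8 and 2.84 CPM, and its bound was 197-fold without severe replicate 1 and 1090-fold without severe replicate 3. Falls were as steep. The cytochrome P450 gene Sobic.002G272700 averaged 374 ± 32.3 CPM in control and had no count in severe, at least 5790-fold lower, and the aminotransferase Sobic.002G041200 was at least 530-fold lower. The aldo-keto reductase gene Sobic.001G274600 had 17914 counts in control and 1 in severe, a ratio of 14300 (95% counting interval 2560 to 564000). The glycosyl hydrolase gene Sobic.008G080400 fell from 594 ± 247 to 0.202 ± 0.176 CPM.

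In all, 14858 of 22356 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment between severe and control, 7057 higher and 7801 lower, and 13358 of them changed at least 2-fold. Total-count scaling gave 5497 higher and 7888 lower. The larger side turned with only these 2 groups in the fit (6360 higher, 6299 lower), with voom weighted per group (6195 and 6062) and in the authors' calls (7733 and 7378). The groups did not overlap in 72.1% of tested genes, where chance gives 10%. The number was 15162 without severe replicate 1, and the authors' deposited adjusted p-values called 15111, which included 13977 of the 14858. Of the 5 families called (fry called 127), only Usp passed without control replicate 2, HSP70 and NB-ARC were also lost without severe replicate 1, and AP2 without control replicate 1, moderate replicate 1, severe replicate 1 or severe replicate 3. Without severe replicate 2, 12 families passed.

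Severe against moderate stress tested directly what differed between the 2 salt levels. SPX genes were lower in severe than in moderate leaves in 8 of 9 and higher in 0, with a median log2 change of -4.21 (camera with Benjamini-Hochberg adjusted p = 0.0114, and adjusted p = 0.658 with an estimated correlation). Sobic.010G138800 (chromosome 10, 23209632 to 23214961) averaged 6.03 ± 1.85 CPM in control, 49.5 ± 29.3 in moderate and 0.33 ± 0.418 in severe (0.0952 without severe replicate 2). Of 33 DUF6 proteins 22 were lower and 3 higher, with a median of -3.1. NB-ARC genes were lower in 119 of 208 and higher in 21, and Sobic.005G222900 went from 57.7 ± 11.5 CPM in moderate to 0.144 ± 0.0755 in severe. HSP70 chaperones were higher in 13 of 20 and lower in 0, heat shock factors higher in 14 of 22 and lower in 4, universal stress proteins higher in 15 of 23 and lower in 3 and AP2/ERF factors higher in 44 of 86 and lower in 13. The heat shock list passed camera (Benjamini-Hochberg adjusted p = 0.000173), and not with an estimated correlation (adjusted p = 0.474). The other 3 lists did not pass: catalases had 2 higher and 0 lower, lipoxygenases 6 and 2 (3 and 3 with total-count scaling) and thaumatin-like proteins 12 and 4. In PP2C (31 higher, 18 lower), bZIP_1 (22 and 17), NAC (27 and 19), Na_H_Exchanger (5 and 2) and K_trans (10 and 7) the larger side turned with total-count scaling.

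Several single genes differed steeply between the 2 salt levels. The transporter gene Sobic.004G282900 (MFS_1) averaged 7.33 ± 5.18 CPM in control (4.52 without control replicate 3), 538 ± 294 in moderate and 0.141 ± 0.0632 in severe. The Myb gene Sobic.009G253300 averaged 47.5 ± 4.77 CPM in moderate and had 2 counts over the severe libraries, a ratio of 1100 (95% counting interval 304 to 9070). The protein kinase genes Sobic.007G214300 and Sobic.002G174801 had no count in severe and were at least 411-fold and 952-fold lower than in moderate against 3 counts over the group. Sobic.001G363100, a universal stress protein gene, averaged 12.7 ± 6.39 CPM in control, 0.295 ± 0.155 in moderate and 65.8 ± 40.2 in severe. Sobic.007G003500 had no count in moderate and was at least 54200-fold higher in the pooled severe libraries (29600 without severe replicate 1 and 85700 without severe replicate 3). That bound does not hold for each severe library. Sobic.007G003200, a FAD-binding oxidoreductase gene, was at least 2820-fold higher in the pooled severe libraries, which read 392.5, 25.6 and 5.96 CPM singly. The pooled bound was 451-fold without severe replicate 1, 4240 without replicate 2 and 4390 without replicate 3. The T2 ribonuclease gene Sobic.002G278700 had 2 counts in moderate and 28213 in severe, a ratio of 25400 (95% counting interval 7030 to 210000), and its severe libraries read 1.33, 78.2 and 1547 CPM, so the ratio was 2120 without severe replicate 3 and 40300 without severe replicate 2.

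In total 14130 of 22356 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment between severe and moderate, 6624 higher and 7506 lower. Total-count scaling moved the median of all genes by -0.775 on the log2 scale and gave 3729 higher and 10094 lower. The larger side turned with voom weighted per group (5702 higher, 5457 lower) and in the authors' calls (7303 and 7294). Of 188 families 11 passed camera with Benjamini-Hochberg adjustment: Usp, HSP70, heat shock factors, AP2, RRM_1, zf-CCCH and Mito_carr as higher, and NB-ARC, DUF6, Peptidase_S10 and ANF_receptor as lower. None passed with an estimated correlation (adjusted p = 0.888 each). At least 11 families passed in 4 of the 10 splits of the severe and moderate libraries into 3 and 3, the real one included. The ANF_receptor family, the ligand-binding domain of glutamate-receptor-like channels, had 11 of 16 lower and a median of -2.91, or -2.28 with genes at 0 set to their bound. Peptidase_S10 was lost without severe replicate 2 or 3. RRM_1 (95 of 203 higher, 31 lower) turned to 42 higher and 48 lower with total-count scaling, and RRM_1, zf-CCCH, Mito_carr, ANF_receptor and Peptidase_S10 lost their calls with it.

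Genes that passed at both stress levels moved mostly the same way. Against control, 1070 genes were higher and 1336 lower at both levels, where independent lists of these sizes would share 631 and 638. With total-count scaling the larger side turned, to 1868 higher and 548 lower at both levels, and it turned without moderate replicate 1 (543 and 530), 2 (644 and 623) or 3 (570 and 528). In opposite directions went 359 genes that were higher in moderate and lower in severe, and 136 lower in moderate and higher in severe, where independent lists would share 697 and 577. Of the 3825 moderate calls, 62.9% were called the same way in severe. Sobic.010G164400, Sobic.003G350700 and Sobic.009G161800 rose at both levels, and Sobic.010G219500 and Sobic.003G387800 fell at both. Both comparisons share the 3 control libraries, which are too few to divide. In 20 simulations of unchanged groups sharing 3 controls, 0 genes were called in both (246 on average, 217 to 276, reached an unadjusted p under 0.05 the same way, against 4277 observed). With no gene changed, almost no adjusted call was due in any case. Groups with separate effects and shared controls were not simulated, so the part that sharing adds to the overlap is not known. The Pearson correlation of the 22356 log2 changes at the 2 levels was 0.346 across genes, which are not independent replicates, and shared controls alone gave 0.501 in the simulations. Their covariance of 1.38 exceeded the simulated 0.146 (0.143 to 0.153) by 1.23. The simulation gave each gene its mean over all 9 libraries in every group. Genes near 0 in control and high elsewhere therefore had better-measured controls there than in the data. The excess thus does not measure effects common to both levels. The number called the same way at both levels, 2406, was 995, 1057 and 1255 without control replicates 1, 2 and 3, 1073, 1267 and 1098 without moderate replicates 1, 2 and 3, and 4437 without severe replicate 1.

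**Figure D3:**
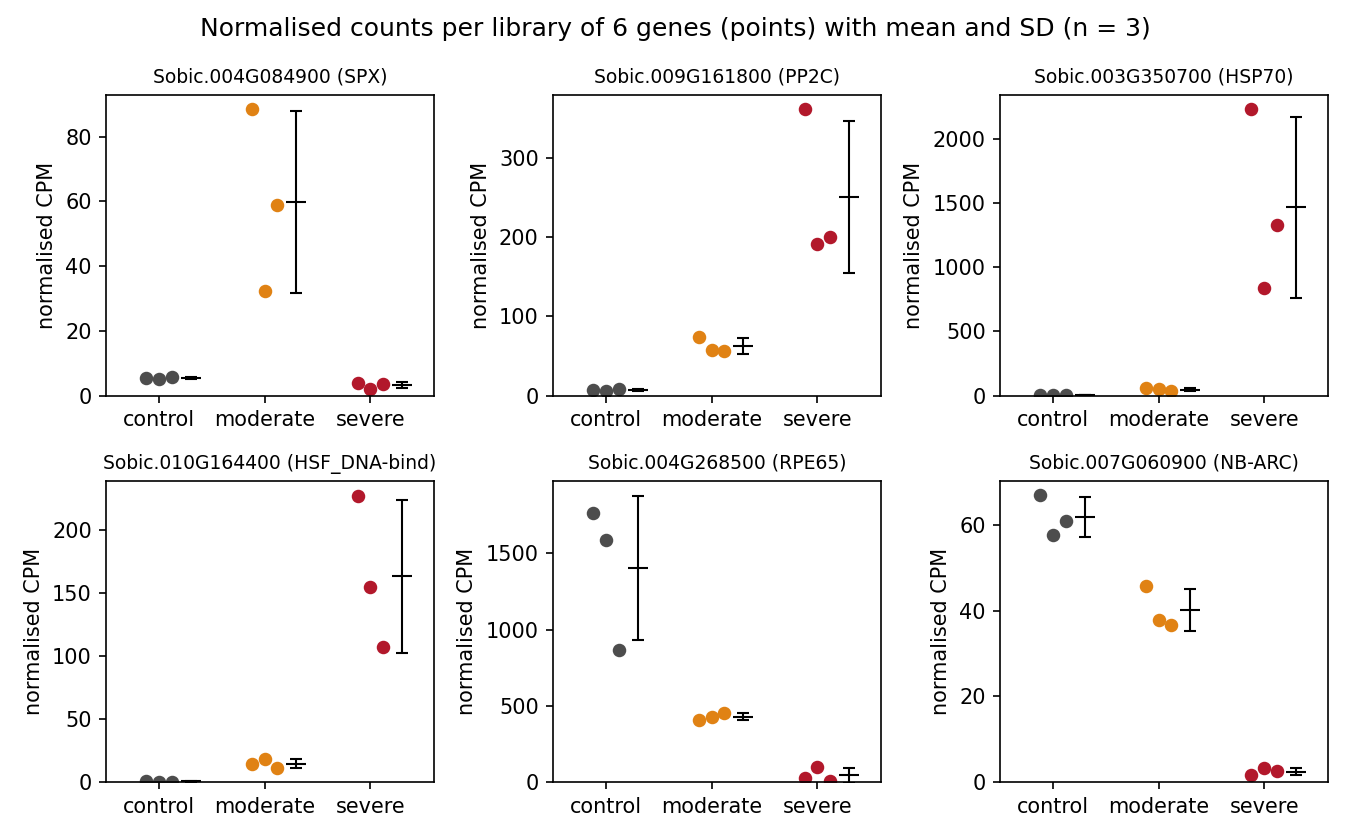
Normalised CPM (vertical axis, from 0) in each of the 9 libraries (points, by group) of 6 genes named in the text, with the group mean and SD (n = 3) beside them. Sobic.004G084900 is highest in moderate (59.9 CPM), Sobic.009G161800, Sobic.003G350700 and Sobic.010G164400 in severe, and Sobic.004G268500 and Sobic.007G060900 in control.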

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

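The families and genes here drew attention because the effects of the 2 stress levels against the same controls differed in a test of severe against moderate, and the severe libraries because of their principal component scores and scaling factors. Of the tests in this part, the family tests, that of SPX among them, were chosen after the values were seen. The other tests of explanations were set down before their own values were computed, with group means, spreads and scaling factors already known. All family calls below are lost with an estimated correlation (adjusted p = 0.888, SPX 0.658).

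Genes with the DUF6 domain differed by a median log2 of -3.1 (camera with Benjamini-Hochberg adjusted p = 0.00477), from 0.90 in moderate and -1.17 in severe against control. The RNA recognition motif family RRM_1 differed by 0.496 (adjusted p = 0.00548), from -0.28 and 0.335, and with total-count scaling the median was -0.286. AP2/ERF factors differed by 1.32 (adjusted p = 0.00548), from -0.0106 and 0.761. HSP70 chaperones differed by 1.58 (adjusted p = 0.00271), from -0.07 and 1.47. By edgeR's quasi-likelihood test, Sobic.009G253300 (Myb) differed by -9.91 on the log2 scale (-9.28 without severe replicate 3; 2 counts in severe, ratio 1100, 95% counting interval 304 to 9070), as it rose by 5.05 in moderate and fell by 4.86 in severe (change of -4.21 without severe replicate 3). Sobic.001G363100 (Usp) differed by 7.76, having changed by -5.39 and 2.37. Sobic.005G222900 (NB-ARC) differed by -8.54, from 2.11 and -6.42. Sobic.010G138800 (SPX) differed by -7.11, from 3.03 and -4.08. Without severe replicate 2 it differed by -9.27 from moderate and -6.24 from control, and without severe replicate 3 by -6.44 and -3.39. Its call in moderate was lost without any 1 of the control libraries (adjusted p = 0.0926, 0.0764 and 0.0615) or moderate replicate 1 or 3 (0.0916 and 0.0609), while the rise stayed at 2.80, 3.13, 3.19, 2.49 and 3.15. Sobic.004G282900 (MFS_1) differed by -11.77, from 6.20 and -5.57 (6.89 and -4.89 without control replicate 3). The protein kinase gene Sobic.002G174801 had no count in severe and was at least 952-fold lower than in moderate. The adjusted p of these 6 genes was 0.00023 or lower, and each was higher or lower in 3 of 3 severe libraries than in 3 of 3 moderate ones.

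The severe libraries lay apart from the others and severe replicate 1 the most, with a scaling factor 0.559 times the mean of the other 2. A few genes taking most of the counts is argued against: without the 100 genes of highest share, which held 29.6, 23.6 and 22.6% of counts in severe replicates 1 to 3, the ratio was 0.618, under the bound of 0.7. Loss of RNA by length stays open, because the rank correlation of gene length with severe replicate 1 over the other 2 was -0.105, between the bounds set for and against, and the table's lengths are genomic spans. Severe replicate 1 may be further along the same response: its difference from the other severe libraries correlated over genes with their response to stress at r = 0.324, where the same measure was -0.523 and -0.347 for severe replicates 2 and 3. Each library is set against the mean of the other 2, so the 3 values are tied and the negative ones are no separate evidence. A response further along was not separated from loss of RNA. It is a hypothesis found and tested on the same libraries, and no record of each plant's condition was used here.

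SPX genes were higher in moderate and not in severe, with a median of 3.03 against -0.157, a difference of -4.21 (camera with Benjamini-Hochberg adjusted p = 0.0114). A single moderate library as the whole source is argued against: without moderate replicate 1, the highest, 6 of 9 SPX genes still passed as higher, which is exactly the bound set beforehand. Without control replicate 2 fewer passed than that bound. Leaving out any control or moderate library also cut the calls over all genes, so such counts reflect power as well. The mean log2 CPM of the 9 genes was also at least 3.92 in each moderate library and at most 1.43 in each control. The choice of scaling is too small a source, as total counts move the median of all genes by 0.477 in moderate against control and -0.775 in severe against moderate, where the SPX medians were 3.03 and -4.21. A response of these phosphate-linked genes to moderate stress may underlie the pattern, but growing conditions that differ between groups, such as soil phosphate, are not given in the sources used here and were not tested.

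More NB-ARC genes were lower than higher in severe, with a median log2 of -1.34 against control and -1.58 against moderate (camera with Benjamini-Hochberg adjusted p = 0.000574). The median against control lay at percentile 0.26 of 10000 lists matched on abundance and gene length (26 lists as low). That is past the bound set against these 2 as the whole source. The lists were drawn gene by gene, so the percentile holds only if NB-ARC genes vary independently. It does not decide the matter for genes that move together. The matched lists had a median of -0.775 (95% of them from -1.17 to -0.392), so part of the fall is shared by genes of like abundance and length. Severe replicate 1 alone is argued against as the source of the gap to all tested genes. Without it the median still lay -0.954 from theirs, past the bound of -0.8. The family's camera call against control was lost, and no matched lists were drawn without that library. A lower level of resistance-receptor transcripts in severe leaves may be a response to the stress, with reads shared between paralogs untested and open.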

How the results depend on the processing

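Total-count scaling, voom with a weight per group and each alternative for the family counts were chosen after the data were seen. Unless stated, the cause was not tested. Genes changed between moderate and control numbered 3825, but 6191 with DESeq2, 10079 with voom weighted per group and 9503 with the 2 groups alone, a fit whose spread, filter and scaling all leave out the severe libraries. Leaving out 1 library gave 1488 (control replicate 1) to 7368 (severe replicate 1). The other alternatives gave 3387 to 4977. The main fit shares 1 spread, with a coefficient of variation of 39.8%. That is wider than in control and moderate (24.7 and 26.3%) and narrower than in severe (60.8%). Such a spread makes moderate against control stricter, and severe contrasts looser, than each group's own spread would. Voom weighted per group went that way, with 10079 for moderate and 12257 for severe against control. Severe against control stayed at 12257 to 15881 and severe against moderate at 11159 to 15191 under each alternative run, leave-one-out included. Genes called the same way at both levels numbered 3763 with DESeq2 and 995 (without control replicate 1) to 4437 (without severe replicate 1), and the correlation was 0.306 (without severe replicate 3) to 0.377 (without control replicate 1). Families called, in the order moderate and severe against control and severe against moderate, were 0, 0 and 0 with an estimated correlation and 57, 127 and 115 by fry, which asks another question. The 2 groups alone gave 30 for moderate, no low-count filter 3 for severe and total counts 6 for severe against moderate. Leave-one-out ranges were 15 to 23, 1 (without control replicate 2) to 12 (without severe replicate 2), and 10 to 13. Gene lists called were 0, 0 and 0 with an estimated correlation, 2, 2 and 2 by fry, and without single libraries 0 to 1 (1 without control replicate 3), 1 and 1. Not every library correlated best with its own replicate number, a hint from the data and not the design: r exceeded 0.1 in 6 of 9 same-number pairs and 3 of 18 others, so pairing is neither shown nor excluded. With the number as a block 3533, 14606 and 13915 genes passed. Of 92 named gene and comparison pairs none reversed. All but 1 were called in the main analysis. The groups of called genes do not overlap, so leaving out a library could hardly reverse them. The pairs were also picked from these same data by their changes, so their stability says nothing of other genes. Under leave-one-out 814 results stayed on their side of the threshold, 13 lost it, some with a larger fold, and 1 gained it, against 457, 2 and 1 under the other settings. The 13 losses fell on Sobic.004G250700, Sobic.006G061300 and Sobic.001G517700. The 92 pairs leave out the moderate call of Sobic.010G138800, whose leave-one-out losses are given above and are not in this tally. Of 35 called family and comparison pairs, leave-one-out kept 287 and lost 28, and the other settings kept 192 and lost 53, among them bZIP_1, DUF6 and zf-Dof in moderate and AP2 and NB-ARC in severe without a filter, and Fer2 and FKBP_C with the block. In none did camera's direction reverse, but the RRM_1 median changed sign with total counts. Depth limits genes under 0.134 to 0.169 CPM. The alternatives planned for the ABA lists were not run, as the lists were empty.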

Other observations

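Members of hormone-response and cell-division families were counted, and none of these families passed camera where it was run. Over all tested genes 66.5% were called in severe and 17.1% in moderate against control. More calls in severe than in moderate, here and in the next paragraph, are therefore not particular to a family. Of 24 auxin response factors (Auxin_resp) 14 were lower and 4 higher in severe than in control, with a median log2 change of -1.19. Under moderate stress 0 were lower and 3 higher. Of 19 response regulators (Response_reg), a family that includes those of cytokinin signalling but is not limited to them, 8 were lower and 4 higher in severe. Under moderate stress 5 were lower and 3 higher, which turned to 3 and 4 with total-count scaling. Both genes of the DNA replication helicase family (MCM) fell in severe and neither passed in moderate. Of 34 core histones (Histone) 14 rose and 6 fell in severe and 4 rose and 0 fell in moderate. Of 32 kinesins (Kinesin) 8 rose and 9 fell in severe.

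Of 13 chalcone and stilbene synthases (Chal_sti_synt_N) 6 fell and 3 rose in severe, with a median of -3.48, or -3 with genes at 0 set to their bound. Of 10 sulfate transporters (Sulfate_transp) 6 fell and 4 rose. Of 67 WRKY factors (WRKY), linked to defence, 30 rose and 14 fell in severe and 5 rose and 4 fell in moderate. Of 34 glutathione S-transferases (GST_N) 9 rose and 6 fell in severe, or 8 and 8 with total-count scaling. Of 8 glutathione peroxidases (GSHPx) 5 rose and 3 fell in severe and 2 fell in moderate. Both ferritins (Ferritin) were higher in severe than in moderate, and neither passed against control at either level. None of these families passed camera in any comparison in which its size let it be tested.

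How often other splits of the same libraries gave as large a result was counted for each model. The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. In moderate against control 1 split, the real one, gave 3825 genes or more, and the highest other gave 0 (at most 437 at an unadjusted p under 0.05). In severe against control it was 1 split, with 14858 genes and a highest other of 0 (786 unadjusted). In severe against moderate it was 1 split, with 14130 genes and a highest other of 0 (1102 unadjusted). Family counts were matched or passed more often: by 3 splits for moderate (19 families, highest other 27), 8 for severe (5, highest other 15) and 4 for severe against moderate (11, highest other 21), the real split included. List counts were reached by 10, 9 and 9 of the 10 splits (0, 1 and 1 lists, highest others 1, 3 and 2). The number of families or lists called therefore does not set the real grouping apart from other splits. Of 100 drawn splits of the 9 libraries into 3 groups of 3, 1 gave as many genes called the same way at both levels (2406, highest other 1), so chance can be excluded only as a grouping of libraries without any effect. Other splits mix the groups, which adds their differences to the spread and leaves few calls, so nothing is read from this about sharing between the levels. For the correlation of the log2 changes 60 of the 100 gave as large a value (0.346, highest other 0.923). A split can put severe libraries into the control group, which adds their difference to both comparisons. That count therefore cannot decide whether chance explains the correlation.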
